A study of Mus musculus with 2 samples.

How the data were processed

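RNA from 2 pools of granulosa cells, 1 from Esr2+/- and 1 from Esr2-/- mice treated with PMSG for 48 h, was compared on 2 dye-reversed two-colour Agilent 60-mer oligonucleotide arrays. Per the labels' protocols, RNA was extracted with TriZol and cleaned on RNeasy columns, 500 ng of total RNA was amplified into Cy3- or Cy5-labelled cRNA, and 750 ng of each cRNA was hybridised for 17 h. The series' design text states that there was 1 biological replicate per genotype and that the arrays are technical dye reversals.

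The deposited scanner files give spot and background intensity in both channels, and per the file headers they were made with Agilent Feature Extraction A.7.5.1. Its processed signals were background-subtracted with spatial detrending and dye-normalized, per the file headers; the method codes are not spelled out there. The deposited LogRatio values are log10 of red over green, and the deposited error-model p-value of each log ratio covers measurement error of the spot only. The deposited series table holds log2 values, which matched the scanner log ratio of the same array within 0.001 for 99.8% of spots on both arrays. Its columns are red over green, not turned to one genotype direction, with medians of 0 on array 1 and 0.0022 on array 2; no further centring was found.

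The following was computed from the scanner files in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Mean spot intensities were background-corrected with normexp (offset 50) using the median local background, and normalized by loess within each array with control spots at weight 0. Control spots and spots flagged as non-uniformity or population outliers (58 on array 1 and 95 on array 2) were left out. Saturated spots were kept; there were 3 in the null channel of array 1 and 2 in the het channel of array 2. The offset pulls ratios of dim spots toward 0. The ratio of array 2 was turned in sign, so that both arrays read null over het, and the arrays were averaged as 1 replicate, which cancels a dye effect that is equal on both. Spots of a probe were averaged. Where a gene had several probes (131 genes) the brightest stood for it.

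Of 20868 probes, 8947 were named by matching the accession in the files, without versions, to the RefSeq gene table of GRCm38.p6, and 604 by a symbol in the file's description that the table holds. The other 11317 probes kept the name in the files. On outlier flags 146 probes were left out. The remainder made 20589 genes or unnamed transcripts, and 18539 passed the background filter (well above background in at least 1 genotype's channel on both arrays). The number of arrays limits the precision, and the SD printed after ± is over the 2 technical hybridisations.

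With 1 pool per genotype no model was fitted and no p-value computed. A gene counted as higher or lower when its mean log2 ratio was at least 1 in size, both arrays gave at least 1.5-fold that way, it passed the background filter, and it was not saturated in both channels on both arrays. The rule was applied to unturned red over green ratios as a technical yardstick. Tested on simulated data made from the real arrays' 18539 genes, it called 0% of genes planted at 1.5-fold, which lies below its threshold, 100% of those planted at 2.5-, 3- and 4-fold, and 0 of 18339 unchanged genes. Nothing was planted between 1.5- and 2.5-fold, so calls near the 2-fold threshold, where many called genes lie, were not tested. The simulated noise was normal, with a robust SD per brightness bin. It lacked the rare large differences between the real arrays, such as that of Inha (SD 1.20), and any variation between pools, so it does not measure false calls from these. For each of 13 pathway lists and 9 cell type lists, the median log2 ratio was set against medians of 10000 random lists of the same size, matched on mean brightness in 20 bins. The random lists were drawn regardless of gene function, so they do not allow for genes of a list that vary together. The percentile describes these arrays only.

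The lists, the size rule, the alternatives and the rule for named genes were fixed before the data were examined. Genes were named as follows: Esr2; up to 15 highest and 15 lowest genes with a symbol among those passing; in each list the members that passed, at most 4, or the member with the largest absolute ratio where none passed; and, always, Fshr, Lhcgr, Cyp19a1, Cyp11a1, Inha, Inhba, Star, Pgr, Ptgs2, Adcyap1r1, Esr1 and 1 further gene, which is not reported here. Genes outside that rule are said to be chosen after their values were seen. Alternatives were the scanner software's log ratio, the series table values, no background subtraction, median centring in place of loess, well above background in both genotypes, no background filter, the mean over probes and each array alone; for the counts also a 1.5-fold threshold and an error-model p under 0.01 on both arrays. A second oocyte list and a list of granulosa identity genes were added after the first results were seen. Probe sequences and a genome were not used here.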

Results

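Granulosa cells are the somatic cells that surround the oocyte in the ovarian follicle, and they are the main site of estrogen receptor beta (ERβ, encoded by Esr2) in the ovary. The series asked how the granulosa cell transcriptome differs between mice without ERβ and their heterozygous controls after treatment with pregnant mare serum gonadotropin (PMSG), which acts like follicle-stimulating hormone (FSH) and drives follicles to the preovulatory stage. Female C57/Bl6 mice aged 23 to 25 days received PMSG for 48 h, and their granulosa cells were pooled by genotype into 1 Esr2+/- (het) and 1 Esr2-/- (null) RNA sample. The pools were compared directly on 2 two-colour Agilent oligonucleotide arrays with the dyes reversed. The null pool was labelled with Cy5 on array 1 and with Cy3 on array 2. All ratios below are null over het, and ratios not given as a fold are log2 ratios. The arrays are technical repeats of 1 pool per genotype, so each SD covers hybridisation and dye only, no test across animals was possible and no p-value is given.

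Each array held 21318 non-control spots. In the null pool 93.0% of them were well above background on array 1 and 90.1% on array 2, and in the het pool 87.2% and 95.1%. After probes were joined into genes, 18539 genes or unnamed transcripts passed the background filter, of which 8609 had a gene symbol. The pools were close to each other in the ratios used here, with 98.8% of these genes within 0.5 log2 units of equality. The offset pulls ratios of dim spots toward 0, so this share may partly reflect the processing. Across genes, which are not independent replicates, the log2 ratios of the arrays correlated with r = 0.32, and with r = 0.44 in the brightest 25%. The SD of the mean ratio over genes was 0.136, against 0.097 for that part of the ratio that differs in sign between the arrays.

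The targeted gene was read first. The Esr2 probe (NM_010157) had a log2 ratio of -0.50 on array 1 and -0.46 on array 2, a mean of -0.48 ± 0.03 (SD, n = 2 technical hybridisations), or 1.40-fold lower in the null pool. It was well above background in both pools on both arrays. The het pool carries 1 intact copy, and the position of this probe relative to the disrupted part of the gene is not known here. A probe outside that part checks nothing, so this value does not test the genotype labels. Esr1, which encodes estrogen receptor alpha, had a log2 ratio of 0.04 ± 0.01.

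By the size rule (a mean change of at least 2-fold, and at least 1.5-fold the same way on each array), 7 genes or transcripts were higher and 17 lower in the null pool. Of these 24, 12 had a gene symbol. The largest falls were in 2 related extracellular matrix glycoproteins of the thrombospondin family. Thbs4 (thrombospondin 4, NM_011582) fell 6.15-fold (log2 ratio -2.62 ± 0.47), and Comp (cartilage oligomeric matrix protein, NM_016685) fell 5.12-fold (-2.36 ± 0.63). The log2 signal of Comp in the null pool was near background (6.34, against 8.69 in the het pool), and the scanner software's ratio was -3.96, so the size of its fall is uncertain. The membrane-bound carbonic anhydrase gene Car14 fell 3.33-fold (-1.73 ± 0.11). Cyp19a1, which encodes aromatase, the enzyme that makes estradiol from androgens, fell 2.42-fold (-1.27 ± 0.20). Inhba, which encodes the beta A subunit of inhibin A and activin A, fell 2.24-fold (-1.16 ± 0.50). Slc38a3, an amino acid transporter gene, fell 2.32-fold (-1.21 ± 0.48). Mug1, a protease inhibitor gene, fell 2.13-fold (-1.09 ± 0.05). A probe for the related murinoglobulin transcript M65237, named after its value was seen, gave -1.11 ± 0.12. Murinoglobulins are close copies of each other, so which of them fell is uncertain.

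Among named genes, the highest ratio was that of Nid2 (nidogen 2, a basement membrane glycoprotein, NM_008695), which rose 2.49-fold (log2 ratio 1.32 ± 0.03). Fabp4, a fatty acid carrier gene, rose 2.39-fold (1.26 ± 0.31), the fibrillar collagen gene Col11a1 rose 2.24-fold (1.16 ± 0.22) and Cyp1b1, whose product hydroxylates estradiol, rose 2.04-fold (1.03 ± 0.38). The probe assigned to Erdr1 by its description rose 2.29-fold (1.20 ± 0.02). The other 2 higher transcripts had no symbol and were chosen for mention after their values were seen. They were AK030678, described in the files as a homolog of an insulin-like growth factor binding type protein, at 1.84 ± 0.17, and M15442, described as myelin proteolipid protein, at 1.69 ± 0.02.

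**Figure D1:**
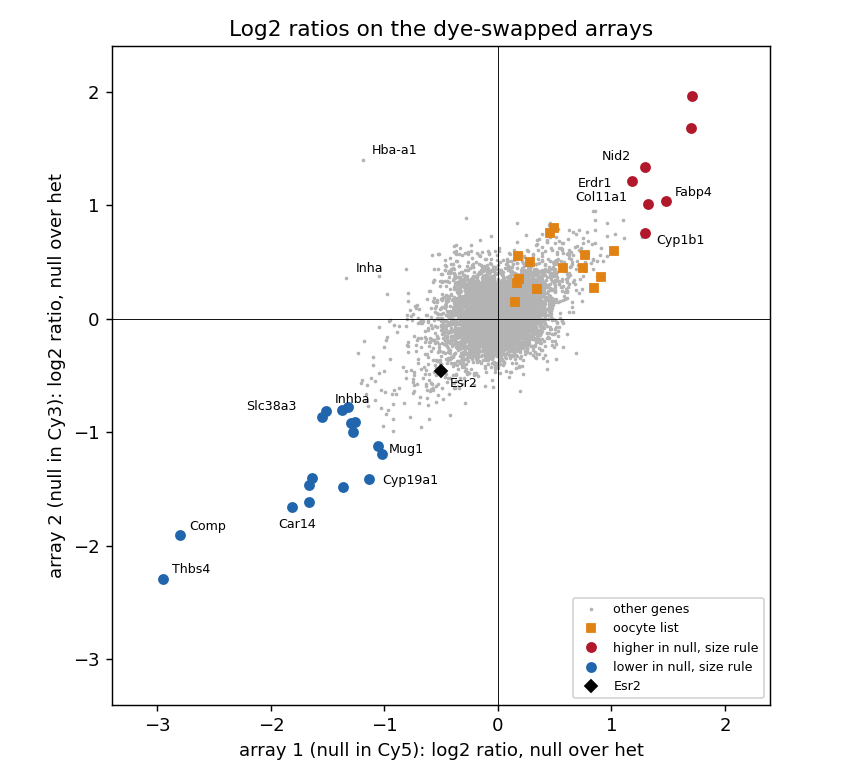
Log2 ratio of each gene, null over het, on array 1 (x axis, null in Cy5) against array 2 (y axis, null in Cy3), after both were turned the same way, for genes that passed the background filter. Red and blue points are the 7 higher and 17 lower genes of the size rule, orange squares the 14 measured oocyte genes, and the black diamond Esr2. Hba-a1 and Inha lie off the diagonal because the arrays gave opposite signs.

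The same rule applied to unturned ratios, where a genotype effect cancels and a dye effect adds up, passed 1 gene. It was the alpha globin gene Hba-a1 (log2 red over green -1.19 and -1.40), named after its values were seen. With array 1 alone the counts were 12 higher and 40 lower, and with array 2 alone 7 and 10. With array 2 alone Inhba (-0.81), Slc38a3 (-0.87), Cyp1b1 (0.76) and 5 transcripts without a symbol were below 2-fold. Under median centring Cyp1b1 (0.98) and Col11a1 (1.11) no longer met the size rule. The scanner software's own log ratios gave 26 higher and 45 lower, with 8 genes passing unturned. All 24 genes above were among them, and there Comp reached -3.96 and Slc38a3 -1.99.

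The list of FSH-driven granulosa differentiation genes, fixed before the data were examined, had a lower median in the null pool. Of 18 measured members, Comp, Cyp19a1 and Inhba fell, none rose and 15 did not pass the size rule. On both arrays 11 members had negative and 5 had positive ratios. The median was -0.22, at percentile 0 of 10000 random lists matched on brightness, and -0.39 with the scanner software's ratios. Array 2 alone did not place the list outside the central 95% of random lists (median -0.05, percentile 7.7), whereas array 1 alone did (-0.35, percentile 0). Below the threshold, Cyp11a1, the enzyme that starts steroid synthesis by cleaving the cholesterol side chain, had -0.91 ± 0.17, and its second probe gave -0.82. The FSH receptor gene Fshr had -0.17 ± 0.11. Lhcgr, the luteinizing hormone (LH) receptor gene, had -0.13 ± 0.18 at a level near background, and -0.51 with the scanner software's ratios. Inha, the inhibin alpha subunit gene, had -1.34 on array 1 and 0.36 on array 2, so its direction was not settled. The members were not uniform, and Akap12, a kinase anchoring protein gene, had 0.48 ± 0.04.

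The steroid synthesis and cholesterol synthesis lists had lower medians in the null pool, though their members were not uniform. Of 14 measured members of the steroid synthesis and cholesterol uptake list, only Cyp19a1 passed the size rule, and the median was -0.08 (percentile 0.11). Ratios were negative on both arrays for 8 members and positive on both for 0. Star, which encodes the protein that carries cholesterol into mitochondria, had -0.02 ± 0.04 at a level near background, with -0.09 in the scanner software's ratios and 0.05 under median centring, so its direction was not settled. Of 11 measured cholesterol synthesis genes none passed, 6 had negative ratios on both arrays and 1 had positive ratios on both. The positive member was Fdft1 (0.38 ± 0.06), named after its value was seen, and the others had opposite signs on the arrays. The list median was -0.15 (percentile 0.01), and -0.24 with the scanner software's ratios. The member farthest from 0 was Fdps, which makes farnesyl diphosphate, at -0.55 ± 0.22. With array 2 alone neither list lay outside the central 95% of random lists, with the steroid list at percentile 33.4 and the cholesterol list at 4.92. The luteal list, which shares Cyp11a1, Star and Akr1c18 with the steroid list, had a median of -0.08 (percentile 0.96, but 13.3 with array 2 alone and 3.37 under median centring), and its member farthest from 0 was the prolactin receptor gene Prlr at -0.96 ± 0.26.

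Genes of hypoxia and glycolysis were also lower as a group. None of 11 measured members passed the size rule, but 7 had negative ratios on both arrays and 1 had positive ratios on both. The median was -0.18 (percentile 0) and lay below the central 95% in all 9 alternative settings, with -0.26 on array 1 alone and -0.10 (percentile 1.41) on array 2 alone. Pgk1, the glycolytic phosphoglycerate kinase gene, had -0.69 ± 0.10.

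Oocyte genes, fixed as markers of a contaminating cell type, had the highest list median. None of 14 measured members passed the size rule, but all 14 were higher in the null pool on both arrays. The median log2 ratio was 0.54 (1.45-fold, percentile 100), with 0.48 on array 1 and 0.45 on array 2. Gdf9, an oocyte growth factor gene, had 0.81 ± 0.30. Named after their values were seen, the egg coat genes Zp2 and Zp3 had 0.66 ± 0.15 and 0.64 ± 0.38. These transcripts were higher in the null pool, whereas the gene groups above had lower medians there, in the same pair of pools.

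Other markers differed less. The ovarian surface epithelium list had a median of 0.13 (percentile 99.7, and inside the central 95% of random lists with array 1 alone), with Cdh1, the E-cadherin gene, at 0.49 ± 0.01 and, in the scanner software's ratios, 0.83. The stroma and smooth muscle list had a median of 0.11 (percentile 98.6), with the proteoglycan gene Dcn at 0.39 ± 0.06. The stroma list was not outside the central 95% of random lists with array 1 alone (median 0.02, percentile 60.4), under median centring (95.2) or with the scanner software's ratios (97.0). The leukocyte (0.02), erythroid (0.02), endothelial (-0.03), theca (-0.03) and Sertoli (-0.01) medians lay inside that range. Within them the members farthest from 0 were Lyz2, a macrophage lysozyme gene, at 0.46 ± 0.05 (0.73 in the scanner software's ratios), Hbb-bt at 0.21 ± 0.44, Egfl7 at -0.17 ± 0.01, Nr2f2 at -0.27 ± 0.21 and Rhox5 at -0.20 ± 0.02 (-0.39 in the scanner software's ratios).

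Immediate early and heat shock genes, which respond to acute stimulation and to cell handling, lay higher in the null pool as a group. None of 15 measured members passed the size rule, 8 were positive on both arrays and 1 was negative on both. The median was 0.14 (percentile 100), and 0.25 with the scanner software's ratios. The heat shock gene Hsph1 had 0.45 ± 0.42 and the transcription factor gene Egr1 had 0.36 ± 0.15. The list of less mature and cumulus granulosa genes had a positive median of 0.11 (percentile 99.5) over 9 measured members but a negative mean of -0.12, and of its members Slc38a3 fell while the other 8 did not pass. With array 2 alone its percentile was 89.3.

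The TGF-beta, BMP and WNT list had a median of -0.04 (percentile 0.93) over 26 measured members, of which only Inhba passed the size rule. That median was 0.01 under median centring and lay at percentile 62.8 with array 2 alone, so the direction of this list is not settled. Genes of cAMP production and signalling, the pathway downstream of the FSH receptor, had a median of -0.01 (percentile 27.7) and a mean of 0.02 over 21 measured members, none passing. The ovulatory response list, made of genes that LH induces, had a median of -0.02 (percentile 20.5) over 17 measured members, none passing. Pgr was not well above background in either pool on either array, and Ptgs2 and Adcyap1r1 were so on at most 1 array in each pool, so no fold is given for these 3 genes.

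Nuclear receptor genes had a median of -0.03 (percentile 4.92) over 22 measured members, none passing, and Nr5a2, which encodes liver receptor homolog 1, had -1.18 on array 1 and -0.19 on array 2 (mean -0.69 ± 0.70). Cell cycle genes (22 measured, median 0.00409) and apoptosis genes (21 measured, median 0.02) lay inside the random range with no member passing. Ccnb2, a mitotic cyclin gene, had -0.37 ± 0.08, and Bbc3, a pro-apoptotic gene, had 0.30 ± 0.11 (0.49 in the scanner software's ratios). Of 19 measured extracellular matrix and basal lamina genes Nid2 rose, and the list median of 0.02 lay inside the random range. In total 6 of the 22 lists lay below the central 95% of random lists, 5 above and 11 inside it. The lists overlap, so these counts are not independent results. Counting the lists added later, 12 of 18 measured FSH-driven, 6 of 14 steroid, 4 of 6 luteal and 5 of 26 TGF-beta, BMP and WNT members are also in another list. Cyp11a1 is in the FSH-driven, steroid and luteal lists, Cyp19a1 in the FSH-driven and steroid lists, and Inhba in the FSH-driven and TGF-beta lists. Random lists hold genes drawn regardless of function, so lists of genes that vary together can lie outside the central 95% more often. These percentiles describe the arrays of 1 pair of pools and are not tests of genotype.

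**Figure D2:**
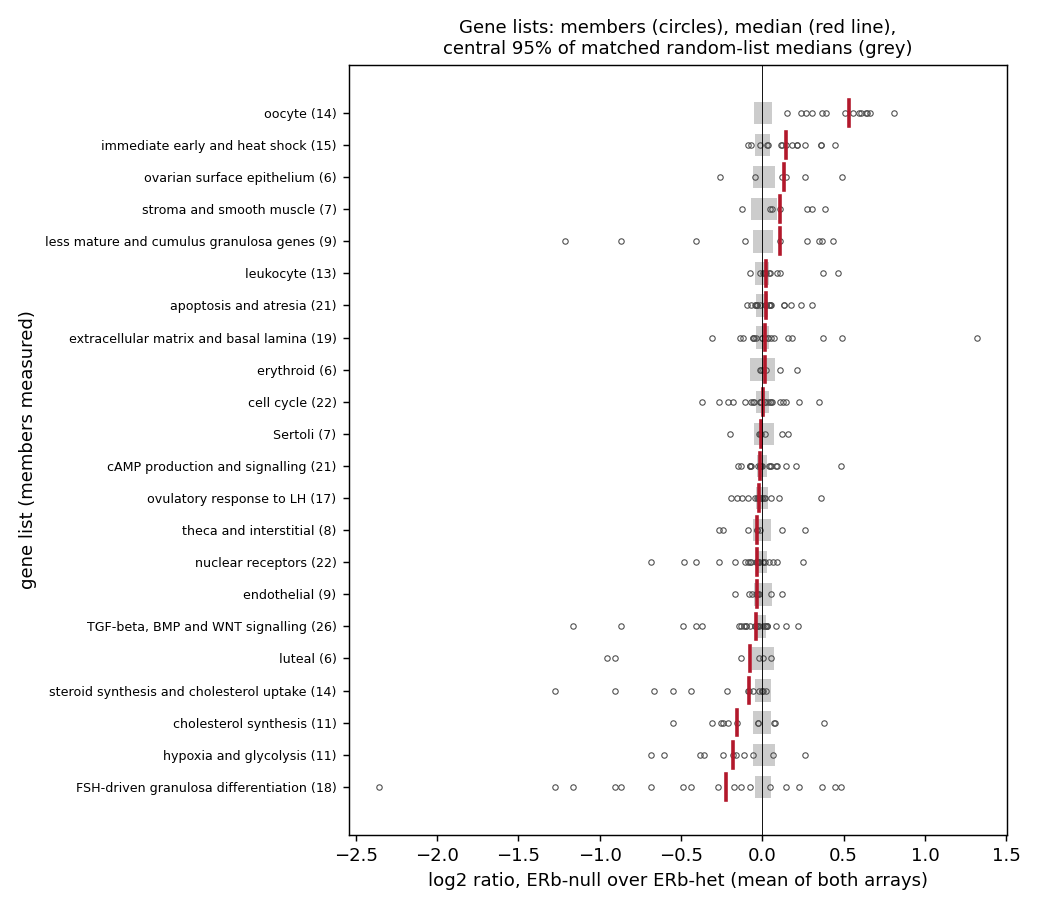
Log2 ratio, null over het (x axis, mean of both arrays), for the measured members of each of the 22 gene lists (y axis, with the number measured). Circles are genes, red lines list medians and grey bars the central 95% of medians of 10000 random lists matched on brightness. The oocyte list lies highest (median 0.54) and the FSH-driven list lowest (-0.22).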

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

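All alternatives here were planned before the data were examined. The counts of 7 higher and 17 lower genes became 26 and 45 with the scanner software's log ratio and with the series table values, 37 and 50 at the 1.5-fold threshold, and ranged from 7 to 12 higher and from 10 to 40 lower with 1 array alone; the cause of the larger counts was not tested, apart from the lower threshold. Median centring gave 5 and 18, with 5 and 17 of the genes shared; no background subtraction, both other background filters, the mean over probes and an error-model p under 0.01 on both arrays gave the same 7 and 17. The Esr2 ratio of -0.48 became -0.67 with the scanner software's and series table values and -0.42 under median centring. The oocyte median of 0.54 became 0.63 with the scanner software's and series table values, 0.51 under median centring and with no background filter, and ranged from 0.45 to 0.48 with 1 array alone. The immediate early and heat shock median of 0.14 became 0.25 with the scanner software's and series table values. Of the 11 lists outside the central 95% of random lists, 3 stayed outside on the same side in all 9 alternatives (oocyte, immediate early and heat shock, hypoxia and glycolysis), and the FSH-driven, steroid and cholesterol synthesis lists in 8, array 2 alone being the exception. The 9 alternatives are not independent checks. The series table repeats the scanner software's ratios. Both other background filters and the mean over probes left the FSH-driven and cholesterol synthesis medians unchanged. Only the settings with 1 array alone separate the arrays. The TGF-beta, BMP and WNT median of -0.04 turned to 0.0125 under median centring; the cause was not tested. The nuclear receptor list, inside the range at percentile 4.92, went to 1.27 there. Median centring left a correlation across genes of -0.69 between the turned arrays. Over both arrays the median of all genes lay between -0.00455 and -0.00126 in each setting. Signal over background limits the dim genes: Lhcgr had -0.13, against -0.51 in the scanner software's ratios, and the cause was not tested. No paired analysis was possible because there was 1 pool per genotype.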

Other observations

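The genes named in the next 2 paragraphs were chosen after their values were seen. Between 1.5- and 2-fold, with the same direction on both arrays, several genes lay lower in the null pool. Hbegf, a ligand of the epidermal growth factor receptor, had a log2 ratio of -0.82 ± 0.25 (SD, n = 2 technical hybridisations), and Ltbp1, which holds latent TGF-beta in the matrix, had -0.92 ± 0.10. The secreted glycoprotein gene Olfm1 had -0.90 ± 0.03, the fatty acid elongase gene Elovl6 had -0.89 ± 0.12 and Perp, a p53 target, had -0.98 ± 0.05. Hsd3b1, which makes progesterone from pregnenolone, had -0.66 ± 0.11. Of the 87 genes or transcripts past 1.5-fold, 37 were higher and 50 lower, 44 had a symbol, and 1 passed when the arrays were left unturned.

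On the other side, Serpinf1, an inhibitor of angiogenesis, had 0.98 ± 0.17 and the transcription factor gene Klf2 had 0.90 ± 0.07. The haptoglobin gene Hp had 0.86 ± 0.01, Agtr2, an angiotensin II receptor gene, had 0.75 ± 0.04, and the small GTPase gene Gem had 0.77 ± 0.01. Several other genes of this size are known from oocytes, among them Oas1d (0.71 ± 0.05), Oas1e (0.70 ± 0.11) and Bcl2l10 (0.66 ± 0.06). Oas1d and Oas1e are close copies, so their signals cannot be assigned with certainty.

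Of the tests below, those of the second oocyte list, the number of pools and the genes near Esr2 were set before their own results were seen. The dye tests of lists, the test of array 1, the comparison with other cell types and the reading of the granulosa identity list were chosen after. All 14 measured oocyte genes were higher in the null pool, and a dye effect is argued against, because the smaller of the array medians was 0.45, above the central 95% of that array's random lists. A lower share of granulosa cells would raise all other cell types alike. It is argued against as the only cause of the oocyte rise, because the highest median of 6 other cell type lists was 0.13 (surface epithelium). In the scanner software's ratios, to which the offset was not applied, that median was 0.22, against 0.63 for the oocyte list. Several of those markers were dim (mean log2 brightness 6.78 for Nr2f2, 7.22 for Cdh1 and 7.39 for Lyz2). The presence of those cells was not tested, so a lower share is not excluded. A second oocyte list sharing no gene with the first had a median of 0.31 over 11 measured members, at percentile 100, with 7 positive and 0 negative on both arrays. It was added after the first results were seen, and it holds Oas1d and Bcl2l10, named above among the genes past 1.5-fold. It is therefore not independent evidence, and more oocyte RNA in the null pool is a candidate explanation only. Gdf9 of the first list had a log2 signal of 12.7 in the null and 11.9 in the het pool, and Oas1d of the second list 11.3 and 10.6, and neither passed the size rule. The second list was not uniform. Members near 0, named after their values were seen, were Ybx2 (-0.01), Cpeb1 (0.004), Obox6 (0.03), Pou5f1 (0.03) and Stk31 (0.04). Whether such RNA would come from more oocytes released at isolation or from follicles at another stage stays open, as does genotype itself, with 1 pool each.

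The FSH-driven list lay lower in the null pool. A dye effect equal on both arrays cancels in their mean, and it is argued against as the only cause because the list median over that mean was -0.22 (percentile 0). The shared sign of the array medians adds little, since array 2 alone lay inside its random range. A dye effect that differs between the arrays is not excluded. An error of array 1 alone stays open for the list median, because array 2 alone gave -0.0549, inside its random range. A lower share of granulosa cells also stays open: 6 granulosa identity genes had a median of 0.16, but 3 of them are in the less mature and cumulus list and the other 3, with a median of -0.07 and an SD of 0.11, are in the FSH-driven list itself, so none is independent of both lists. The 3 genes alone lay above the FSH-driven median by 0.15, more than their SD, and that reading is not used because they are part of the list to be explained. The 6 other cell type lists did not rise alike (medians from -0.03 to 0.13), but several of their markers were dim, so they do not settle the granulosa share either. A difference between the pools unrelated to genotype, such as follicle stage or response to PMSG in the mice pooled, cannot be told apart from genotype with 1 pool per genotype.

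Sequence from embryonic stem cells of another strain may flank a targeted allele and change nearby genes. Among 76 measured genes within 10 Mb of Esr2 (neighbours taken from the GRCm38.p6 gene table) the mean absolute log2 ratio was 0.0802, at percentile 36.5 of 458 other windows, whose 95th percentile was 0.127. None of the 76 passed the size rule, which says little because only 24 of all 18539 genes or transcripts did. Their ratios ran from -0.23 (Rab15) to 0.45 (Tgfb3), genes named after their values were seen. The het pool also carries 1 targeted allele, so both pools would hold such flanking sequence. The data thus showed no excess of differences around Esr2, which does not exclude an effect on single genes.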
